A study of Bombyx mori with 12 samples.

How the data were processed

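Gene expression was measured by paired-end sequencing of poly(A) RNA from the cephalothorax of Bombyx mori, in 12 libraries of 4 groups. Groups were taken from the sample labels for molting type and batch, and libraries are named by group and replicate number. Per the submitters' processing notes, reads were handled with Trimmomatic 0.39, HISAT2 2.2.1, StringTie 2.2.1 and DESeq2 1.38.3, while the labels' extract protocol names another version of HISAT2. The deposited count table holds whole-number counts per gene and library that were not normalized, per the file headers and values, and the deposited FPKM table holds the authors' length and depth scaled values of the same gene IDs in another order. The counting program, the genome build, the annotation and the use of strand are not given in the sources used here. The FPKM column of batch 1 trimolter 2 was empty and was the 1 column per library left unused, so FPKM values of 11 libraries were used. They gave 1 alternative test, and with the counts they gave the relative gene lengths used to leave out numbered loci and to check for a length trend.

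The count table had 17583 rows. Of these, 14945 matched the RefSeq gene table of assembly ASM3026992v2, which was used for names only and not for coordinates, and 1441 carried a symbol other than a LOC number, a microRNA or a tRNA. A further 511 rows were loci that the authors numbered as additions to the annotation, with 0.21% to 0.264% of the counts of a library. They were left out of library sizes and tests, because a number did not stand for 1 locus: the length implied by count and FPKM differed between batches by more than 0.1 log2 units for 24 of 24 such loci with a value in both batches and for 0 of 8055 other genes, and within a batch for 0 of 162 and 0 of 8409. This choice was made after the data were examined.

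Counts were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 with TMM factors, after filterByExpr by group, which left 10721 genes. All 12 libraries entered 1 model with a mean per group, and 6 contrasts were tested: tetramolters against trimolters in each batch, their mean, their difference (batch 2 minus batch 1), and batch 2 against batch 1 in trimolters and in tetramolters. P-values were adjusted by Benjamini and Hochberg within a contrast, with a threshold of 0.05, and changes of at least 1 log2 unit were counted as well. Standard errors of log2 fold changes came from the fitted weights and moderated dispersion of the same model. Values in CPM are counts scaled by library size after TMM, with their SD over 3 libraries. Tests are 2-sided. With 1 to 3 counts summed over a group, the ratio is given with an exact 95% interval, which covers counting error only, as do all statements on depth, since reads carried no molecular identifiers.

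Designs, contrasts, list patterns, the rule for named genes and most alternatives were fixed before the data were examined. The patterns of 27 gene lists were turned into gene symbols after the files could be read and before any test. The lists cover ecdysteroid synthesis, ecdysone response, juvenile hormone synthesis, juvenile hormone response and turnover, Hox, cuticle proteins, chitin metabolism, melanin and tanning, heat shock, DNA replication and cell cycle, cytosolic ribosomal proteins, oxidative phosphorylation, glycolysis, lipid metabolism, insulin and TOR signalling, circadian clock, immunity, detoxification, chemosensation, autophagy and cell death, and markers of silk gland, fat body, midgut, muscle, nervous system and eye, haemocytes, and trachea. Lists with at least 3 tested members, 23 of them, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, on log2 CPM with a prior count of 2, and the 138 p-values were adjusted together. Of these tests 17 passed, 0 with an estimated correlation in camera (2 at an unadjusted p under 0.05) and 50 in fry, which asks whether the genes of a list move one way without comparing them with other genes.

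Genes named for size were, per contrast, the 8 largest rises and 8 largest falls among called genes with a symbol other than a LOC number, a mean of at least 1 log2 CPM and group ranges that did not overlap. For the mean this held in both batches in 1 direction, and for the difference in both batches. Product descriptions, which the rule first named, were not given in the sources used here, so a symbol stood for a name, and genes without one were passed over, up to 58 in 1 direction. Key hormone genes and Scr were named whatever their test, and up to 4 members per list by smallest p. Groups did not overlap for 53.7%, 55.6%, 31.1% and 71.5% of genes in batch 1, batch 2, trimolters and tetramolters, where chance gives 10%.

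Replicates were compared before averaging, and every pair of replicates differed by more than sampling noise. The tests were checked on simulated counts with 200 changed genes per contrast. At a change of 1 log2 unit, 64% were recovered for batch 1, 63% for batch 2, 78% for the mean, 25% for the difference, 57% for trimolters and 57% for tetramolters. At 2 units the shares were 88%, 92%, 97%, 83%, 90% and 90%, with 5 to 12 false calls per contrast. The simulated groups shared 1 dispersion per gene, and fewer genes changed than were called in the data. In the data the mean SD per gene was 0.408 log2 units in batch 1 trimolters and 0.168 to 0.256 in the other groups. The simulation therefore does not give the error rate of contrasts with the batch 1 trimolters. Alternatives were RLE and upper quartile factors, no filter, a filter of 50 counts, DESeq2 1.42.0, limma-voom, a fit to the compared groups alone, a block for replicate number, limma on log2(FPKM + 1) for genes with an FPKM of at least 1 in 3 libraries, glmTreat at 0.58 log2 units, and leaving out each library.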

Results

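Poly(A) RNA of pooled head and thorax tissue (the cephalothorax) was sequenced from larvae of the silkworm Bombyx mori, strain Guangri 3, collected at the molt that ends the third instar. This strain is a dominant trimolter: most larvae spin after the third molt, while some, the tetramolters, molt once more. The cephalothorax holds the prothoracic glands, which make ecdysteroids, and the corpora allata, which make juvenile hormone. The 12 libraries formed 4 groups of 3: trimolters and tetramolters in each of 2 labelled batches. Library totals ranged from 13449541 to 15650612 counts. The study collected larvae in spring and, at higher temperature, in autumn. The series text calls the spring group A, and an A stands in the titles of all batch 1 libraries and of none of batch 2, but no label states a season for a batch, so results are given by batch. Season, temperature, photoperiod and sequencing batch cannot be told apart. The titles use A for trimolters and TA for tetramolters in batch 1, and T for trimolters and F for tetramolters in batch 2, and no label explains the letters, so groups follow the labelled molting type. The series text names 3 silkworms per group and season, but no label ties a library to 1 animal. The p-values thus measure the spread between these libraries, pooled over the 4 groups, and that spread may be technical in part.

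On the first principal component, with 47.7% of the variance, both trimolter groups lay between the 2 tetramolter groups, as the plot of principal components shows. Batch 1 trimolter 1 correlated less with its replicate 2 (0.9365) than with batch 2 trimolter 1 (0.9406). Replicate libraries of the batch 1 trimolters correlated less (Pearson r across genes of log2 CPM 0.937 to 0.967) than those of the batch 1 tetramolters (0.99 to 0.991), the batch 2 trimolters (0.978 to 0.981) and the batch 2 tetramolters (0.978 to 0.983). The mean SD per gene was 0.408 log2 units in the batch 1 trimolters, against 0.168, 0.235 and 0.256 in the other groups in that order. The share of counts in cuticle protein genes ranged from 7.54% to 14.609% over the 3 batch 1 trimolter libraries.

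**Figure D1:**
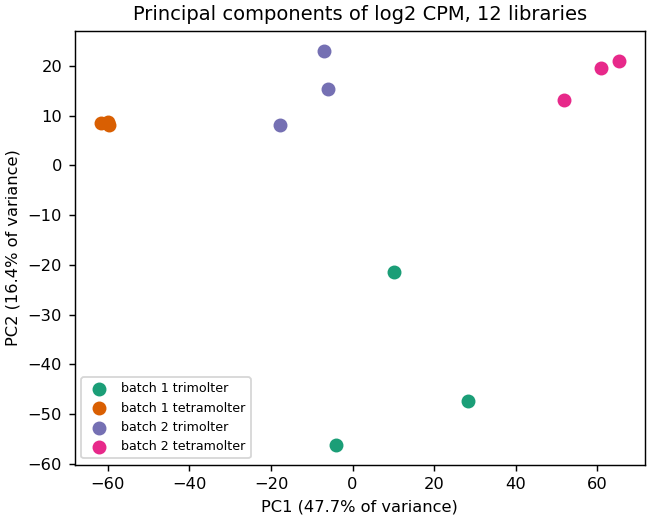
First and second principal components of log2 CPM of the tested genes, with the percent of variance on each axis; each point is 1 library, coloured by group (n = 3 per group). The batch 1 tetramolters lie at the low end of the first component (-61.78 to -59.73), the batch 2 tetramolters at the high end (51.88 to 65.24) and all 6 trimolter libraries between -17.86 and 28.18.

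The first comparison asked which transcripts differed between tetramolters and trimolters within batch 1. In the tetramolters, genes of the cuticle fell and genes of the ribosome rose. Of 161 cuticle protein genes, 93 fell and 12 rose, with a median log2 fold change of -1.56. CPR38 went from 5649 ± 1114 CPM in trimolters to 1089 ± 27.4 CPM in tetramolters (SD, n = 3 each), and CPG5 from 645 ± 197 to 64.5 ± 4.73 CPM. Of 79 cytosolic ribosomal protein genes, 76 rose and 2 fell, with a median of 1.06, and RpS29 rose from 79.6 ± 4.21 to 409 ± 51.2 CPM (log2 fold change 2.36, SE 0.14, edgeR adjusted p = 3.66e-06). Adjusted over the list alone, 99 cuticle protein genes fell and 12 rose, and the ribosomal counts were 76 and 2. Both lists passed camera with a preset correlation (adjusted p = 9.23e-10 and 4.52e-28), and neither passed with an estimated correlation (adjusted p = 0.893 for each). Markers of muscle moved in the same samples: 5 of 10 rose and none fell, among them Projectin (1.37), TpnI (1.33) and Titin2 (1.34, its call lost in a fit to these groups alone), while the list passed camera only without batch 1 trimolter 1 (adjusted p = 0.012, against 0.238 with all libraries). Markers of other tissues were called too: 2 of 5 fell for midgut (1 when adjusted over the list alone), 2 of 8 for haemocytes, 2 of 2 for trachea and 1 of 2 for fat body. For the nervous system and eye 1 of 7 rose, and for silk gland 1 of 2. As 4849 of all 10721 tested genes were called here, these marker counts do not set a tissue apart. The midgut, haemocyte and nervous system lists did not pass camera (adjusted p = 0.663, 0.995 and 0.82). Their mean log2 CPM changed by -0.299 (SE 0.506), 0.254 (SE 0.108) and 0.934 (SE 0.519).

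Among hormone genes in batch 1, Cyp306a1 (gene ID 100127116), a cytochrome P450 of ecdysteroid synthesis, rose from 17.2 ± 3.35 to 64.4 ± 2.43 CPM in tetramolters (log2 fold change 1.90, SE 0.15, edgeR adjusted p = 1.16e-05). Kr-h1, which juvenile hormone induces, rose by 0.68. MET1, a juvenile hormone receptor gene, fell by 0.87, Jheh2, which encodes an epoxide hydrolase of juvenile hormone, fell by 1.08, and Hmg-r, of juvenile hormone synthesis, fell by 0.57. Of the 7 tested ecdysone response genes, Ftz-f1, E74 and Br-c fell by 0.50, 0.62 and 0.70, E75 rose by 0.35, and EcR (0.07), USP (0.21) and Hr3 (-0.17) did not pass the test. The call for Ftz-f1 was lost without batch 1 tetramolter 1 (edgeR adjusted p = 0.0553). That for E75 was lost without batch 1 trimolter 2 or 3 or any 1 of the batch 1 tetramolters or batch 2 trimolters (edgeR adjusted p of up to 0.124). In other settings, the call of Br-c was lost in limma on FPKM, that of E75 also there, without a filter and in a fit to these groups alone, and those of Ftz-f1 and E74 with the length trend removed. The genes Nvd (0.44), Cyp314a1 (1.13), Cyp302a1 (0.33), Cyp315a1 (0.10), Cyp18a1 (-0.01), P450 (0.18), BmMET2 (0.78), jhe1 (0.32), Jhdk (-0.12) and Scr (-0.25) did not pass, and Cyp307a1 had 5 counts summed over the tetramolters and 1 over the trimolters. PTTH, Jhamt and torso had too few counts to be tested in any comparison.

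In all, 4849 of 10721 tested genes changed in batch 1 (edgeR, adjusted p under 0.05), 2416 higher and 2433 lower in tetramolters, and 1776 of them by at least 1 log2 unit. The 8 named genes with the largest rises were GSTe4, CPG19, Bm122, Dsclp, Lsp-t, CPH27, Time and RpS29, with log2 fold changes from 3.78 (GSTe4) down to 2.36 (RpS29). The 8 with the largest falls were VAP and the cuticle protein genes CPR104, CPR71, CPR39, CPR105, CPFL4, CPR12 and CPH7, from -7.78 (CPR104) to -5.66 (CPH7). CPR39 was at 203 ± 272 CPM in the trimolters. The call of VAP was lost in limma-voom. Of the 12 tested heat shock genes 5 fell and 1 rose, with HSP70 at -2.17 and Hsp90 at -1.52, and the list did not pass camera (adjusted p = 0.247). Of 17 genes of oxidative phosphorylation 8 fell and 3 rose, also when adjusted over the list alone, with the mitochondrially encoded ND5 and ND1 at -2.28 and -2.23 and ND4L, chosen after its value was seen, at 1.69, and the list did not pass camera (adjusted p = 0.376, and 0.0226 without batch 1 trimolter 2). Of its 11 mitochondrially encoded members 7 fell and 2 rose. Of the genes that fell, the calls of COX1 and COX2 were lost without batch 1 tetramolter 2 or 3, and that of ATP6 without batch 1 trimolter 1 or 3 or any 1 of the tetramolters of either batch (edgeR adjusted p of up to 0.0637, 0.0597 and 0.165). The calls of COX1, COX2 and ATP6 were also lost in a fit to these groups alone (edgeR adjusted p = 0.0826, 0.0695 and 0.0873). That of ATP6 was lost with upper quartile factors and in limma-voom as well. Counts of near-identical cuticle protein genes depend on how reads shared between copies were assigned, which is not given in the sources used here.

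**Figure D2:**
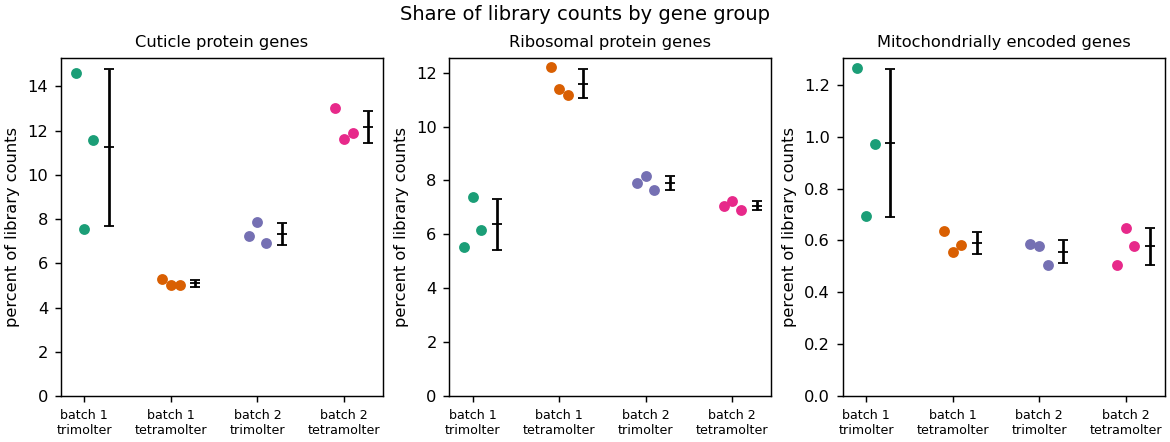
Percent of each library's counts in cuticle protein genes, cytosolic ribosomal protein genes and mitochondrially encoded genes; coloured points are single libraries and the black mark with bars is the mean with its SD (n = 3 per group). Cuticle genes took 11.24% ± 3.55 and 5.093% ± 0.152 of counts in batch 1 trimolters and tetramolters and 7.323% ± 0.484 and 12.17% ± 0.737 in those of batch 2, and ribosomal protein genes 6.364% ± 0.946, 11.59% ± 0.539, 7.903% ± 0.248 and 7.069% ± 0.166 in the same order. Mitochondrially encoded genes took 0.9767% ± 0.286, 0.5903% ± 0.0411, 0.557% ± 0.0443 and 0.577% ± 0.071 in that order.

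The same comparison in batch 2 gave the other direction for the cuticle. Of the 161 cuticle protein genes, 87 rose in tetramolters and 7 fell, with a median log2 fold change of 1.10, and 92 rose and 9 fell when adjusted over the list alone. CPR38 rose from 2420 ± 270 to 10097 ± 1262 CPM (log2 fold change 2.06, SE 0.16) and CPG5 from 149 ± 18.1 to 849 ± 26.3 CPM (2.51, SE 0.18). The list passed camera (adjusted p = 3.87e-10; adjusted p = 0.893 with an estimated correlation). Of the ribosomal protein genes 9 fell and 2 rose, and 68 did not pass. Adjusted over the list alone, 2 rose and none fell, and the median was -0.26 (camera adjusted p = 8.28e-06; adjusted p = 0.95 with an estimated correlation). The call for RpS20 was lost without batch 2 trimolter 1 or any batch 2 tetramolter, and that for RpL27 without batch 2 trimolter 2 or 3 or batch 2 tetramolter 2 or 3 (edgeR adjusted p of up to 0.076 and 0.113).

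More immune and cell cycle genes rose than fell in the batch 2 tetramolters. Of 28 antimicrobial and immune genes 18 rose and 3 fell, and 18 and 4 when adjusted over the list alone (camera adjusted p = 0.00673; adjusted p = 0.893 with an estimated correlation). The antimicrobial peptide genes Attacin1 (4.86, SE 0.78) and CecA (4.23, SE 0.74) rose, with wide spread between tetramolter libraries: Attacin1 was at 75 ± 60.8 CPM and CecA at 18.9 ± 14.1 CPM (SD, n = 3). The call of CecA was lost in limma-voom. Of 16 genes of DNA replication and the cell cycle 8 rose and none fell, and 8 and 1 when adjusted over the list alone, and they included Cyce (1.52), RnrS (1.43), Cdc2 (1.33) and Rpa1 (0.63) (camera adjusted p = 0.0106; adjusted p = 0.893 with an estimated correlation). The chaperone genes Hsp90 and HSP70 rose by 2.35 and 2.01, with 6 of the 12 heat shock genes higher and 1 lower (camera adjusted p = 0.0829, and 0.0375 without batch 2 tetramolter 1). Of the muscle markers 5 fell and 1 rose, and 8 and 1 when adjusted over the list alone, with Projectin at -0.88 (camera adjusted p = 0.0752, and 0.00864 and 0.0238 without batch 1 trimolter 1 and 2).

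Among hormone genes in batch 2, Cyp307a1, which acts early in ecdysteroid synthesis, had 555 counts summed over the 3 tetramolter libraries and 2 over the trimolters, a ratio of 264 after scaling (95% exact interval of counting error 72.8 to 2190). Nvd, which encodes the enzyme that converts cholesterol in the same pathway, rose from 0.222 ± 0.0365 to 3.31 ± 1.96 CPM (log2 fold change 3.85, SE 0.56, edgeR adjusted p = 0.000224). Cyp306a1 fell by 1.08, P450 by 1.18, USP by 0.35, Ftz-f1 by 0.72, and BmMET2, a second receptor gene of the MET type, by 4.06 (SE 0.77). Scr and Hmg-r rose by 0.58 and 0.50. The call of Scr was lost without batch 2 trimolter 2 or 3, that of Hmg-r without any batch 2 trimolter or batch 2 tetramolter 3, and that of USP without batch 2 trimolter 1 or 3 or batch 2 tetramolter 1 or 3 (edgeR adjusted p of up to 0.0671, 0.0947 and 0.111). That of Hmg-r was also lost with upper quartile factors. The other hormone genes did not pass: Kr-h1 (0.15), E74 (0.12), E75 (0.03), EcR (0.28), Hr3 (-0.20), MET1 (0.08), Jheh2 (-0.03), Jhdk (0.67), jhe1 (-0.08), Cyp18a1 (-0.27), Cyp302a1 (0.24), Cyp314a1 (-0.45) and Cyp315a1 (0.28), and the fitted change of Br-c was below 0.01.

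In all, 4042 of 10721 genes changed in batch 2 (edgeR, adjusted p under 0.05), 2092 higher and 1950 lower in tetramolters, and 1383 by at least 1 log2 unit. The largest named rises were those of CPR39, CPR60, CPG3, CPG15, CPR95, Attacin1, CPR71 and CPH32, from 8.34 (CPR39) to 4.75 (CPH32). The largest named falls were those of GSTe4, CPH27, Cyp4m9, Ppbp2, nAChRa7, yellow-11, Cyp9a22 and CPR51, from -3.87 (GSTe4) to -2.10 (CPR51). GSTe4 and CPH27 are also among the largest named rises of batch 1.

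The test of the difference between the batches (batch 2 change minus batch 1 change) passed for 5734 genes in edgeR, 2864 with a higher and 2870 with a lower change in batch 2, and 3775 by at least 1 log2 unit. Across the 10721 genes, which are not independent replicates, the changes of both batches correlated negatively (Pearson r = -0.487, Spearman rho = -0.529), as the plot of changes in both batches shows. Of 2439 genes called in both batches, 2227 (91.3%) moved in opposite directions. There were 1051 genes higher in batch 1 and lower in batch 2, where independent lists of these sizes would share 439.4, and 1176 lower in batch 1 and higher in batch 2, against 474.8. Higher in both were 104 genes, against 471.4, and lower in both 108, against 442.5. These comparisons share no library.

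**Figure D3:**
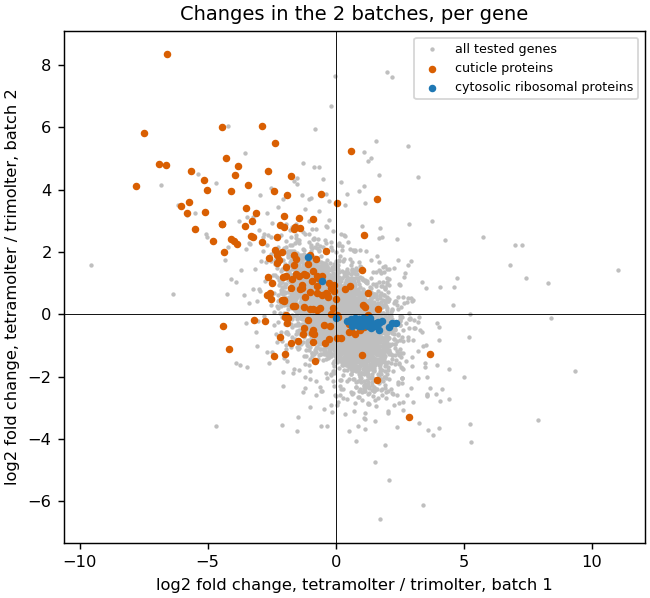
Log2 fold change of tetramolters against trimolters in batch 1 (horizontal) and batch 2 (vertical); grey points are the 10721 tested genes, orange points the cuticle protein genes and blue points the cytosolic ribosomal protein genes. Most cuticle protein genes lie to the upper left (medians -1.563 and 1.1), and most ribosomal protein genes to the right and slightly below 0 (medians 1.063 and -0.263).

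The difference was positive for 106 of the 161 cuticle protein genes and negative for 8 (110 and 10 adjusted over the list alone), with a median of 2.52 log2 units (camera adjusted p = 3.8e-12; adjusted p = 0.893 with an estimated correlation). CPG5, CPR38, CPG4 and CPR3 differed by 5.83, 4.44, 4.40 and 3.25. It was negative for 76 of the 79 ribosomal protein genes and positive for 2, counts that were the same when adjusted over the list alone, with a median of -1.32 (camera adjusted p = 9.08e-21; adjusted p = 0.893 with an estimated correlation). Among these, RpS29 and RpL37A differed by -2.66 and -2.47. Of the 10 muscle markers 7 had a negative and 1 a positive difference, with a median of -1.35 (camera adjusted p = 0.0813, and 0.00679 without batch 1 trimolter 1). Of the cell cycle genes 9 had a positive and 1 a negative difference, also when adjusted over the list alone, with a median of 0.64 (camera adjusted p = 0.0297; adjusted p = 0.893 with an estimated correlation). Cyp306a1 differed by -2.99 (SE 0.21, edgeR adjusted p = 2.43e-06), Nvd by 3.41 (SE 0.77, edgeR adjusted p = 0.00233) and BmMET2 by -4.85 (SE 1.00, edgeR adjusted p = 0.00112). The difference was also positive for Hmg-r (1.07), Jheh2 (1.05), MET1 (0.95), Scr (0.84), E74 (0.74) and Br-c (0.71), and negative for USP (-0.56) and P450 (-1.36). The calls of E74 and Br-c were lost with upper quartile factors, and both without batch 1 trimolter 3, batch 2 trimolter 1 or 3 or batch 2 tetramolter 2 or 3. That of E74 was also lost without batch 1 tetramolter 3, and that of Br-c without batch 1 trimolter 2, batch 1 tetramolter 1 or 2 or batch 2 tetramolter 1, in limma-voom and in limma on FPKM (edgeR adjusted p without 1 library of up to 0.0625 and 0.106). Kr-h1 (-0.53, edgeR adjusted p = 0.058) and Ftz-f1 (-0.23, edgeR adjusted p = 0.396) did not pass, nor did Cyp307a1 (edgeR adjusted p = 0.143), E75 (-0.32), EcR (0.21), Hr3 (-0.03), Jhdk (0.79), jhe1 (-0.40), Cyp18a1 (-0.26), Cyp302a1 (-0.10), Cyp314a1 (-1.58) and Cyp315a1 (0.18). The largest named positive differences were those of CPR39, CPR104, CPR71, CPH7, CPR105, CPFL3, CPR12 and CPR95, and the largest negative ones those of GSTe4, CPH27, CPG19, Time, yellow-11, Bm122, Dsclp and Cyp9a22.

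Averaged over both batches, 1671 genes differed between tetramolters and trimolters (edgeR, adjusted p under 0.05), 919 higher and 752 lower, and 228 by at least 1 log2 unit. Of the ribosomal protein genes 59 rose and none fell, with a median of 0.40, and 76 rose when adjusted over the list alone (camera adjusted p = 5e-29; adjusted p = 0.893 with an estimated correlation). That average joins a rise in batch 1 with a median of -0.26 in batch 2. The protease inhibitor gene serpin-23 rose in both batches, by 1.20 and 2.04 (mean 1.62, SE 0.13, edgeR adjusted p = 0.000116), and serpin-9 fell in both, by 2.61 and 1.55 (mean -2.08, SE 0.26, edgeR adjusted p = 0.00135). The cuticle protein gene CPR61 rose by 1.02 and 1.42 in the batches. Ftz-f1, a nuclear receptor gene of the ecdysone cascade, fell in both (mean -0.61, SE 0.11, edgeR adjusted p = 0.00419).

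Other hormone genes that passed for the mean were Nvd (2.15), Kr-h1 (0.42), Cyp306a1 (0.41), MET1 (-0.39), Jheh2 (-0.56) and BmMET2 (-1.64). Of these Nvd, Cyp306a1, MET1, Jheh2 and BmMET2 also differed between the batches, so their means join unequal changes. Cyp307a1 passed as well, with 1 and 2 counts summed over the trimolters of the batches, and its call was lost without batch 1 tetramolter 1 (edgeR adjusted p = 0.139). The calls of Kr-h1 and Cyp306a1 were lost without any batch 1 tetramolter, batch 2 trimolter 2 or 3 or batch 2 tetramolter 2 (edgeR adjusted p of up to 0.0788 and 0.0834). That of BmMET2 was lost without batch 1 trimolter 2, any batch 1 tetramolter, batch 2 trimolter 1 or 2 or batch 2 tetramolter 1 or 3 (edgeR adjusted p of up to 0.0889), in limma-voom and with the length trend removed. The genes E74 (-0.25), E75 (0.19), EcR (0.18), USP (-0.07), Br-c (-0.35), Hr3 (-0.18), Hmg-r (-0.04), P450 (-0.50), Jhdk (0.27), jhe1 (0.12), Scr (0.16), Cyp18a1 (-0.14), Cyp302a1 (0.28), Cyp314a1 (0.34) and Cyp315a1 (0.19) did not pass.

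The named genes with the same direction in both batches and the largest mean rises were glv4-like, serpin-23, CPR61, Ubx, NGR-A4, Cyp332a1, Alstr and CPR127, from 2.37 (glv4-like) to 0.74 (CPR127). Those with the largest mean falls were CPH13, serpin-9, CPH10, EAAT-2, CPR46, serpin-7, NimB and CPR42, from -2.64 (CPH13) to -0.85 (CPR42). The calls of glv4-like and Ubx were lost without batch 1 tetramolter 1 and batch 1 tetramolter 2 respectively, at edgeR adjusted p of 0.0501 and 0.0536, and that of glv4-like also in limma-voom. The whole count fell to 907 without batch 1 tetramolter 1 and 1054 without batch 1 tetramolter 2.

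Between the trimolters of the batches, 1650 genes differed (edgeR, adjusted p under 0.05), 782 higher and 868 lower in batch 2, and 515 by at least 1 log2 unit. Mitochondrially encoded genes differed unevenly: ND1 went from 251 ± 82.3 CPM in batch 1 to 7.03 ± 2.83 CPM in batch 2 (SD, n = 3) and COX3 from 1808 ± 433 to 471 ± 108 CPM, while COX1, at 3374 ± 1130 and 2686 ± 62.9 CPM, and COX2, at 3177 ± 882 and 2140 ± 208 CPM, both chosen after their values were seen, did not pass. ND2 was at 104 ± 24.1 CPM in batch 1 trimolters and 0.0884 ± 0.101 CPM in those of batch 2. Of 17 tested genes of oxidative phosphorylation 8 fell and none rose (10 fell when adjusted over the list alone), with a median of -0.78 and a mean of -2.06 (camera adjusted p = 1.51e-06; adjusted p = 0.893 with an estimated correlation). All 8 were among the 11 mitochondrially encoded members of the list, and none of its nuclear members was called over all genes. Of 161 cuticle protein genes 39 fell and 4 rose, 45 and 5 when adjusted over the list alone, with CPG5 at -2.11 and CPR3 at -1.13 (camera adjusted p = 0.000107; adjusted p = 0.893 with an estimated correlation). The call of the cuticle list was lost without batch 1 trimolter 1 (camera adjusted p = 0.308). Of 10 muscle markers 1 rose and none fell, and that list passed without the same library (camera adjusted p = 0.00445, against 0.376 with all libraries). Of 8 haemocyte markers 2 rose and none fell (camera adjusted p = 0.614), and their mean log2 CPM was higher by 0.43 (SE 0.141).

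Most ribosomal protein and detoxification genes did not pass in the trimolters, and of those that did more were higher in batch 2. Of the 79 ribosomal protein genes 23 rose and 1 fell, 42 and 1 when adjusted over the list alone, with a median of 0.33 (camera adjusted p = 4.5e-14; adjusted p = 0.893 with an estimated correlation). Of 92 detoxification genes 21 rose and 7 fell, 23 and 8 when adjusted over the list alone, with CCE-un1 at 1.96 and GSTo2 at 0.69 (camera adjusted p = 0.0112; adjusted p = 0.291 with an estimated correlation). UGT33D7 had 220 counts summed over the batch 2 libraries and 3 over those of batch 1, a ratio of 70.9 after scaling (95% exact interval of counting error 24 to 347). Of the hormone genes, BmMET2 (2.38) and Cyp306a1 (1.06) rose, and Hmg-r, Scr and E74 fell by 0.52, 0.59 and 0.64. The calls of BmMET2, Hmg-r, Scr and E74 were lost without batch 1 trimolter 3, that of BmMET2 also without batch 2 trimolter 1 or 2, that of Scr also without batch 2 trimolter 2 or 3, those of Hmg-r and E74 also without batch 1 trimolter 1 or any batch 2 trimolter, and that of Hmg-r also without batch 1 tetramolter 1 or 3 (edgeR adjusted p of up to 0.091, 0.141, 0.12 and 0.112). The others did not pass: Kr-h1 (0.24), Ftz-f1 (-0.18), E75 (0.04), EcR (-0.14), USP (-0.26), Br-c (-0.31), Hr3 (-0.18), MET1 (-0.39), Jheh2 (-0.36), Jhdk (0.31), jhe1 (-0.10), P450 (0.47), Nvd (-1.02), Cyp18a1 (0.31), Cyp302a1 (-0.15), Cyp314a1 (0.48) and Cyp315a1 (0.11), while Cyp307a1 had 2 counts summed over batch 2 and 1 over batch 1. The largest named rises were those of Bm122, Titin1, Ppbp2, nAChRa9, Lsp-t, CLIP3, GSTe4 and CCE-un1, down to 1.96 (CCE-un1). Without batch 1 trimolter 3 the calls of Bm122, Titin1, Ppbp2 and nAChRa9 were lost, without any batch 2 trimolter those of Bm122, Ppbp2, nAChRa9 and GSTe4, and without any tetramolter of either batch those of Bm122 and nAChRa9 (edgeR adjusted p of up to 0.145). The largest named falls were those of ND2, CPR39, ND5, ND1, CPR71, CPR104, CPFL3 and CPH7, from -10.07 (ND2) to -3.29 (CPH7), and the call of CPR71 was lost without batch 2 trimolter 1 or 3 (edgeR adjusted p of up to 0.0522).

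The count for the trimolters rested on which libraries entered. It was 2539, 2704 and 707 without batch 1 trimolter 1, 2 and 3, and 898, 852 and 774 without batch 2 trimolter 1, 2 and 3. A fit to the 6 trimolter libraries alone called 127 genes. In that fit 35 of the 45 named calls were lost, and the 10 left were COX3, ND1, ND2, ND5, CPG5, CPG21, CPR3, CPR104, Cyp306a1 and UGT33D7. The calls of Bm122, GSTe4 and nAChRa9 were lost without a filter, and those of E74, Hmg-r and Scr with the length trend removed.

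Between the tetramolters of the batches, 6275 genes differed (edgeR, adjusted p under 0.05), 3104 higher and 3171 lower in batch 2, and 3100 by at least 1 log2 unit. Cuticle protein genes rose in batch 2: 112 of 161 rose and 9 fell, 115 and 9 when adjusted over the list alone, with a median of 1.93 (camera adjusted p = 1e-12; adjusted p = 0.893 with an estimated correlation). CPR38 was at 1089 ± 27.4 CPM in batch 1 and 10097 ± 1262 CPM in batch 2. Ribosomal protein genes fell: 76 of 79 fell and 2 rose, counts unchanged when adjusted over the list alone, with a median of -0.97 (camera adjusted p = 8.98e-19; adjusted p = 0.893 with an estimated correlation), among them RpL39 and RpS29 by 2.42 and 2.34, while RpL7Ae rose by 2.45. Cell cycle genes rose, 10 of 16 with 1 lower, also when adjusted over the list alone, with RnrS, Cdc2 and Mcm7 at 2.39, 1.78 and 1.01 (camera adjusted p = 0.0119; adjusted p = 0.893 with an estimated correlation). Of 11 tested mitochondrially encoded genes 9 were lower in batch 2, among them ND5 (-2.77), ND1 (-2.47), ATP6 (-1.26), COX3 (-1.22) and CYTB (-0.77), while COX1 (0.20) and COX2 (0.12) did not pass. ATP6, CYTB, COX1 and COX2 were chosen after their values were seen, and the call of CYTB was lost in limma-voom, with the length trend removed and without any 1 of the tetramolters of either batch (edgeR adjusted p of up to 0.117).

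Among hormone genes Cyp307a1 (6.55, SE 0.91), Nvd (2.38), Jhdk (1.11), Jheh2 (0.69), MET1 (0.55) and Hmg-r (0.55) were higher in batch 2 tetramolters. BmMET2, Cyp306a1, P450, USP, Ftz-f1 and E75 fell by 2.47, 1.92, 0.89, 0.82, 0.40 and 0.28, and the calls of Jhdk, Ftz-f1 and E75 were lost without any 1 of the batch 1 tetramolters or batch 2 tetramolter 3, those of Jhdk and Ftz-f1 also without batch 2 tetramolter 2, that of E75 without batch 2 tetramolter 1, and those of Ftz-f1 and E75 without any batch 2 trimolter (edgeR adjusted p of up to 0.0782, 0.157 and 0.155). Those of Ftz-f1 and E75 were also lost in DESeq2, in limma on FPKM and without a filter, that of E75 with RLE factors and that of Ftz-f1 in a fit to these groups alone. The others did not pass: Kr-h1 (-0.30), Scr (0.25), E74 (0.10), EcR (0.06), Br-c (0.40), Hr3 (-0.22), jhe1 (-0.50), Cyp18a1 (0.06), Cyp302a1 (-0.24), Cyp314a1 (-1.10) and Cyp315a1 (0.29). The heat shock genes Hsp23.7, Hsp90 and HSP70 rose by 5.85, 3.38 and 2.95, and 7 of the list's 12 rose and 1 fell (camera adjusted p = 0.0538, and 0.0263 to 0.0492 without any 1 of batch 1 tetramolter 1 or 3, the batch 1 trimolters, batch 2 tetramolter 1 or 3 and batch 2 trimolter 3). With a block for replicate number the heat shock list passed too (camera adjusted p = 0.0394). The largest named rises were those of the cuticle protein genes CPR39, CPR104, CPR71, CPR95, CPR12, CPR105, CPH7 and CPG3, from 9.06 (CPR39) to 6.91 (CPG3). The largest named falls were those of ND2, GSTe4, CPH27, Dsclp, Time, CYP340C1, CPG19 and yellow-11, from -8.33 (ND2) to -3.25 (yellow-11). Muscle markers fell for 6 of 10 genes and rose for 1, with Projectin at -2.57 and TpnI at -1.65 (camera adjusted p = 0.178).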

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

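Of the tests in this part, those without cuticle and ribosomal protein genes, of tissue share, exchanged labels, gene length and mitochondrial share were chosen after the results were seen. Results stand here because the change from trimolter to tetramolter differed between batches in a test of the difference, or because they lie outside the comparisons.

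The difference passed in edgeR for 5734 genes and in camera for 3 lists, with medians of 2.523 for cuticle proteins, 0.637 for DNA replication and cell cycle and -1.319 for cytosolic ribosomal proteins. None of the 3 list calls held with an estimated correlation (camera adjusted p = 0.893 with an estimated correlation for each). With a block for replicate number the immune and heat shock lists passed for the difference as well (camera adjusted p = 0.0494 and 0.0487). In log2 units (batch 2 change minus batch 1 change), named cuticle genes differed by 14.91 (CPR39), 11.9 (CPR104), 11.41 (CPR71), 10.26 (CPH7), 9.52 (CPR105), 9.47 (CPFL3), 9.32 (CPR12), 9.31 (CPR95), 5.83 (CPG5), 4.44 (CPR38), 4.4 (CPG4) and 3.25 (CPR3), and in the other direction by -4.96 (CPG19) and -6.16 (CPH27). Ribosomal protein genes differed by -1.59 (RpL31), -1.68 (RpS15A), -2.47 (RpL37A) and -2.66 (RpS29), and cell cycle genes by 2.97 (Cyce), 2.68 (RnrS), 2.33 (Cdc2) and 1.26 (Rpa1). Hormone genes and Scr differed by 3.41 (Nvd), 1.07 (Hmg-r), 1.05 (Jheh2), 0.95 (MET1), 0.84 (Scr), 0.74 (E74), 0.71 (Br-c), -0.56 (USP), -1.36 (P450), -2.99 (Cyp306a1) and -4.85 (BmMET2). The calls of E74 and Br-c were both lost without batch 1 trimolter 3, batch 2 trimolter 1 or 3 or batch 2 tetramolter 2 or 3, that of E74 also without batch 1 tetramolter 3, and that of Br-c also without batch 1 trimolter 2, batch 1 tetramolter 1 or 2 or batch 2 tetramolter 1 (edgeR adjusted p of up to 0.0625 and 0.106). The others were -3.86 (Cyp9a22), -4.45 (Dsclp), -4.51 (Bm122), -4.54 (yellow-11), -4.61 (Time) and -7.65 (GSTe4).

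Among the numbered extra loci left out of the tests, 17 had at least 100 counts in all 6 libraries of batch 1 and at most 5 in each of batch 2, and 11 the reverse. Of all other genes, 1 and 0 did so. Since a number did not stand for 1 locus in both batches, as given above, these counts do not show loci transcribed in 1 batch only.

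The first pattern is the opposite change in the 2 batches. Cuticle and ribosomal protein genes alone do not carry it: without both lists r was -0.449, past a bound written before that value was seen. A lower share of a main tissue other than muscle stays open. The batch 2 change minus batch 1 change was -1.406 (SE 0.365) for muscle, -0.462 (SE 0.152) for haemocyte and -0.759 (SE 0.612) for nervous system and eye markers. For midgut markers it was 0.546 (SE 0.522), within 2 standard errors of 0. So muscle minus midgut, at -1.952 (SE 0.869), was beyond 2 standard errors from 0 but does not show that midgut moved the other way. Batch 1 alone, at 1.011 (SE 0.854), does not show it either. Between the tetramolters of the batches muscle minus midgut was -1.671 (SE 0.116), with muscle at -0.907 (SE 0.053) and midgut at 0.765 (SE 0.137). These opposite moves argue against the share of a tissue that is neither muscle nor midgut as the whole cause between the tetramolters. They do not bear on a change in the share of midgut, which would itself move the markers apart. A change in the share of muscle or of midgut as the cause was not tested. An exchange of trimolter and tetramolter labels within 1 batch stays open: batch 1 tetramolters correlated more with batch 2 trimolters (0.9448 to 0.9598) than with batch 2 tetramolters (0.8747 to 0.8975), batch 1 trimolters did not differ beyond 2 standard errors (own label minus other 0.0117, SE 0.0093), and the titles, with a T for tetramolters in batch 1 and for trimolters in batch 2, do not settle it. A difference in molting stage at sampling, or a biological difference tied to season, may contribute, and batch and season cannot be told apart.

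The second pattern is the ribosomal protein rise in batch 1 tetramolters. Scaling by a few abundant genes is argued against by a lowest median of 1.045 under other factors. Short genes tended to rise in this comparison (Spearman rho of change with length -0.195 across genes), for the mean (-0.297) and in batch 2 trimolters (-0.194), where more ribosomal protein genes rose than fell as well. Length as the whole cause is argued against, as 72 of 79 genes were still called higher with the length trend removed, although the median fell from 1.063 to 0.672 (SD 0.434 over genes). Length as part of the cause stays open, since other genes of matched length had a median of 0.284, between the bounds set for and against it.

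The third pattern is the fall of mitochondrially encoded genes in batch 2, for 8 of 11 tested in trimolters and 9 in tetramolters (ND2 -8.33, ND4L -5.89, ND5 -2.77, ND1 -2.47, ND3 -2.41, ND4 -1.58, ATP6 -1.26, COX3 -1.22, CYTB -0.77). The call of CYTB was lost in trimolters in a fit to these groups alone and without batch 1 trimolter 3 or batch 2 trimolter 2 or 3 and in tetramolters without any 1 of the tetramolters of either batch (edgeR adjusted p without 1 library of up to 0.0553 and 0.117). Within batch 1, 7 of the 11 were also lower and 2 higher in tetramolters than in trimolters, with ND5 and ND1 at -2.28 and -2.23 and ND4L at 1.69. Of these calls, those of COX1, COX2 and ATP6 were lost without some single libraries. A uniformly lower share of mitochondrial RNA is argued against in trimolters, where the test was run, since over the 8 genes with at least 10 counts in each library the changes spanned 4.83 log2 units, from -5.16 (ND1) to -0.33 (COX1), with standard errors of at most 0.311. In trimolters all mitochondrially encoded genes together took 0.9767% ± 0.286 of counts in batch 1 and 0.557% ± 0.0443 in batch 2 (SD). In tetramolters they took 0.5903% ± 0.0411 in batch 1 and 0.577% ± 0.071 in batch 2. COX1 (0.20) and COX2 (0.12) did not pass there, so a fall of the whole share is argued against in tetramolters too. A difference in poly(A) capture or in how reads of these genes were assigned between batches was not tested, and neither was a biological one.

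Splits of the libraries bear on the counts. For batch 1, batch 2, trimolters and tetramolters, 1 of 10 splits, the real one, gave as many genes (4849, 4042, 1650 and 6275), and the highest others gave 0, 1, 19 and 0. With 10 splits a share under 0.05 cannot be reached. Of 100 splits within batches, 1, the real one, gave as many genes as the difference (5734, highest other 1671). A random grouping of these libraries is thus unlikely to give that count. The splits cannot exclude chance differences between the animals or collections behind the groups, since no label ties a library to 1 animal. For the mean, 2 of 100 gave as many as the real 1671, the real grouping and 1 other. That share is under 0.05, but it does not exclude chance as the source of a difference by molting type. The other, with 5734, is the real grouping with the labels of batch 2 exchanged, and points to a structure of the samples, the opposite changes of the batches. Splits that mix the labels within at least 1 batch gave up to 1602 genes for the mean, close to the real count, so the size of that count alone says little about molting type.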

How the results depend on the processing

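Of the settings in this part, those with the length trend removed, with the numbered extra loci kept and without cuticle and ribosomal protein genes were chosen after the data were seen. The counts of changed genes stayed within 1.5 times under the settings not named here. Testing for a change above 0.58 log2 units (glmTreat) left 1534 genes in batch 1, 1089 in batch 2, 66 for the mean, 3608 for the difference, 129 in trimolters and 3301 in tetramolters, fewer by construction. For trimolters a fit to those groups alone called 127 genes. That fit has fewer libraries to estimate the spread. The main test pools the spread over all groups, and the batch 1 trimolters had the largest (mean SD 0.408 log2 units, against 0.168 to 0.256 in the others). Which of these lowered the count was not tested, so the main p-values for trimolters may understate the spread between those libraries. Limma on FPKM called 2626, but the FPKM values lack batch 1 trimolter 2. Without that library the main test on counts called 2704, so the FPKM scale need not be the source of the higher count. Libraries with the same replicate number deviated from their group means with correlations of -0.042 to 0.114, not all above 0.1, so the numbers were not taken as pairs. Not every library correlated best with its own number. A block for replicate number called 1077 genes for the mean, and under it 0 of the calls named by rule in batch 1, 2 in batch 2 (RpS20 and USP), 2 for the mean (BmMET2 and CPH10), 1 for the difference (AKH2), 2 in tetramolters (E75 and Ftz-f1) and 12 in trimolters did not pass. The call of ATP6 in batch 1, a gene outside that rule, was lost as well (edgeR adjusted p = 0.0635). The immune list gained a call for the mean, the difference and tetramolters (camera adjusted p = 0.0205, 0.0494 and 0.0377). The heat shock list gained one for the difference and tetramolters (camera adjusted p = 0.0487 and 0.0394). The correlation of both batches' changes was -0.614 over highly expressed genes. Of 138 list tests 0 passed in camera with an estimated correlation (2 at an unadjusted p under 0.05) and 50 in fry. Upper quartile factors moved the median change of all genes from -0.011 to -0.138 for the difference and from -0.023 to -0.129 for tetramolters.

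Without 1 library, counts were 3733 to 5414 for batch 1, 3062 to 4820 for batch 2, 907 to 2472 for the mean (907 without batch 1 tetramolter 1), 5184 to 6276 for the difference, 707 to 2704 for trimolters (without batch 1 trimolter 3 and 2) and 5509 to 6805 for tetramolters, r was -0.483 to -0.403, and 18 to 25 list tests passed. Where this leaves a group with 2 libraries, the spread is pooled over groups.

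Calls of named genes were lost in at least 1 setting other than glmTreat or leaving out a library for 13 of 83 in batch 1, 4 of 72 in batch 2, 5 of 43 for the mean, 6 of 89 for the difference, 3 of 99 in tetramolters and 35 of 45 in trimolters, these 35 in the fit to the trimolters alone. In the same order, glmTreat ended 25, 23, 35, 7, 16 and 29 of these calls, and leaving out at least 1 library 9, 12, 11, 3, 9 and 19. A change of sign occurred for 64 values in 28 results, 0 of them called by edgeR with all libraries or under the alternative. In batch 1 these were EcR (-0.067 with FPKM), Cyp18a1 (0.034 with upper quartile factors) and Jhdk (0.107 with limma-voom, 0.092 with the replicate block, 0.499 with FPKM). In batch 2 they were MET1 (-0.006), E75 (-0.061) and Br-c (-0.085) with upper quartile factors, and Br-c without a filter (-0.02) and with a filter of 50 counts (-0.023). With the length trend removed they were Cyp302a1 for the difference (0.072), Hmg-r and USP for the mean (0.046 and 0.024) and EcR in trimolters (0.023). In tetramolters they were E74 (-0.01), EcR (-0.042) and Cyp18a1 (-0.047) with upper quartile factors, and in trimolters E75 (-0.002) with FPKM. The cause was not tested. The FPKM values lack batch 1 trimolter 2, and counts without that library also turned EcR (-0.07) and Jhdk (0.311) in batch 1 and E75 (-0.031) in trimolters.

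Without 1 library the sign changed, in batch 1, for Cyp315a1 (-0.024 to 0.177), EcR (-0.07 to 0.255), Cyp18a1 (-0.124 to 0.032), Jhdk (-0.553 to 0.311) and Hr3 (-0.402 to 0.01). In batch 2 it changed for MET1 (-0.033 to 0.158), E75 (-0.052 to 0.076), Br-c (-0.075 to 0.047), Jheh2 (-0.132 to 0.06), jhe1 (-0.376 to 0.048) and Cyp314a1 (-0.914 to 0.058). For the difference it changed for Hr3 (-0.233 to 0.201) and Cyp302a1 (-0.318 to 0.331), and for the mean for jhe1 (-0.032 to 0.271) and Hmg-r (-0.123 to 0.016). In tetramolters it changed for EcR (-0.046 to 0.193), Cyp18a1 (-0.121 to 0.178) and Cyp302a1 (-0.468 to 0.031). In trimolters it changed for Cyp314a1 (-0.063 to 0.91), Jhdk (-0.092 to 0.751), Cyp315a1 (-0.112 to 0.266), E75 (-0.031 to 0.143), jhe1 (-0.275 to 0.209), EcR (-0.282 to 0.065), Cyp302a1 (-0.569 to 0.018) and Hr3 (-0.415 to 0.019). Genes with few counts, such as PTTH, Jhamt and torso, could not be compared at this depth.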

Other observations

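Members of other gene groups were called between the tetramolters of the batches in edgeR, where 6275 of all 10721 tested genes were called, so the counts that follow do not set a group apart from other genes. Of 8 genes in the insulin and TOR list 4 fell in batch 2 and 1 rose. That list also counts the adipokinetic hormone genes AKH1 and AKH2. InR, the insulin receptor gene, fell from 241 ± 3.5 to 43.2 ± 3.35 CPM (SD, n = 3). Of 5 clock and neuropeptide genes in the circadian list 4 fell, among them Per, from 53 ± 4.82 to 17.5 ± 0.998 CPM, and cry2, from 64.3 ± 0.65 to 40.9 ± 1.89 CPM. Of 13 genes of autophagy and cell death 2 rose and 4 fell, with Atg8 falling from 380 ± 42 to 121 ± 17.7 CPM. Of 28 immune genes 18 rose and 6 fell, of 18 melanin and tanning genes 10 rose and 7 fell, of 21 chemosensory genes 8 rose and 5 fell, of 4 lipid genes 2 rose and 1 fell, and of 17 oxidative phosphorylation genes 1 rose and 10 fell. Among these 17 are 11 mitochondrially encoded genes, of which 9 fell and none rose. Adjusted over the list alone, the counts were 20 and 7 for immune genes and 9 and 5 for chemosensory genes, and unchanged for the other lists named so far. None of these lists passed camera in this comparison with all libraries and no block. With a block for replicate number the immune list passed (camera adjusted p = 0.0377). The immune and oxidative phosphorylation lists (adjusted p = 0.0571 each) passed without some single libraries: the immune list without batch 1 tetramolter 1 or 2, batch 2 tetramolter 1 or batch 2 trimolter 3 (down to 0.00281), and the other without batch 1 tetramolter 2 or 3, batch 1 trimolter 2, batch 2 tetramolter 2 or 3 or batch 2 trimolter 1 or 3 (down to 0.0316).

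None of the lists that follow with at least 3 tested members passed camera in the same comparison (adjusted p from 0.421 for midgut markers to 0.995 for haemocyte markers). Of the chitin metabolism genes, 4 of 8 rose and 1 fell, among them Chi-h, a chitinase gene, from 20.2 ± 3.02 to 146 ± 110 CPM, and Treh-2, from 36.4 ± 3.3 to 89.8 ± 1.87 CPM. Of 11 genes of juvenile hormone synthesis 6 rose and 4 fell, of 15 of its response and turnover 7 rose and 3 fell, of 8 of ecdysteroid synthesis 3 rose and 1 fell, of 7 of ecdysone response 3 fell (1 when adjusted over the list alone), and of 92 detoxification genes 31 rose and 28 fell. Markers of midgut rose for 3 of 5 genes, with Apn4 at 421 ± 41.7 and 1241 ± 200.5 CPM, and those of the nervous system and eye fell for 3 of 7. Of the ecdysone response genes, the calls of Ftz-f1 and E75 were both lost without any 1 of the batch 1 tetramolters or batch 2 trimolters or batch 2 tetramolter 3, that of Ftz-f1 also without batch 2 tetramolter 2 and that of E75 without batch 2 tetramolter 1 (edgeR adjusted p of up to 0.157 and 0.155). Of 8 haemocyte markers 1 rose and 1 fell, and 0 passed when adjusted over the list alone, and the 3 tested Hox genes Ubx (0.84), Scr (0.25) and Dfd (-0.59) did not pass in edgeR. The lists with 2 tested members gave median log2 fold changes of 3.75 for fat body, with both members higher, -2.27 for silk gland, 0.46 for trachea and 0.16 for glycolysis.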
